A study of Mus musculus with 5 samples.

How the data were processed

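RNA from cultured mouse cortical neurons of 5 samples was sequenced, 2 with a PQBP1-targeting hairpin and 3 with a non-targeting one, per the labels. The labels do not say whether samples of a group came from separate cultures, so the authors' p-values may rest on technical spread. RNA was extracted on RNeasy columns and libraries were made from polyA RNA with the PrepX mRNA kit of IntegenX, per the labels' protocols. Reads were aligned with TopHat2 2.0.4 to mm10, per the submitters' processing notes. How junction reads were counted, which test gave the p-values, which filters were applied and whether replicates were pooled are not given in the sources used here.

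The authors deposited a table of alternative splicing events that gives, per the file headers, a gene name, an event and junction identifier, a chromosome, strand, start and end, a p-value and a log2 fold of knockdown over control for each junction. The deposited p-value is the authors' own and is taken as unadjusted, since the header names no adjustment. The deposited log2 fold is read here as a change in relative use within the event. This follows from the values: in all 408 events with 2 junctions both junctions have the same p (to a relative tolerance of 1e-06) and opposite signs. The table has 1402 junctions in 585 events, and 13 junctions have an empty p. There are no counts, inclusion levels or values per sample, so no sample-level test could be made, and the depth per sample and the precision it gives are unknown. The design had foreseen counts or inclusion levels as well, and the tests for a table of the authors' own comparison were used.

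Positions in the table were compared with introns of GENCODE M21 on the same assembly. Reading the start as the last base of the left exon and adding 1 to start and to end gave introns of which 1179 (84.1%) equal an annotated intron. Of the 1402 junctions, 1326 have an annotated donor and 1345 an annotated acceptor. Events of 2 junctions were typed from the annotated exons at the 2 differing sites as cassette exon, cassette of several exons, alternative 5' or 3' splice site, mutually exclusive exons, alternative first or last exon, other, or site not annotated. Types of the authors were not given in the table, so these types and the exon identities are a reconstruction. Where several annotated exons fitted the same junctions the shortest was taken, which concerns 16 of 224 cassette exons. Events with 3 or more junctions (177, in 165 genes) were counted but given no direction. Of these, 63 had junctions with p under 0.05 in both directions, 51 in the upward and 63 in the downward direction alone.

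The change of a 2-junction event is the log2 fold of the nearer junction minus that of the farther one, which is the log2 change of their ratio. It is called higher or lower after its sign, and for cassette exons a positive sign means more inclusion. Direction within an event type was tested with an exact two-sided binomial test against an equal split for types with at least 6 events. Direction across types was tested with Fisher's exact test, and size with a two-sided permutation test of the difference in medians (100000 resamples). The smallest p these permutations can give is 1e-05. Exon length, the share of exons of 27 nt or shorter, the share with a length that is a multiple of 3, and exon GC content from the GENCODE transcripts were compared between directions with Fisher's exact test or the permutation test. Adjustment followed Benjamini and Hochberg within each family, and the threshold was 0.05. Intervals are 95% Wilson intervals and cover counting of events, which are not independent replicates. The relative use of the 2 junctions in each group was inferred from their folds, taking the 2 uses to add up to the whole. The junction with the larger absolute fold is the one with the lower use averaged over the groups, and it was taken as the rarer. Taking the rarer by use in mock, in knockdown or in both groups alike was added after seeing the data, and the average and mock disagree in 23 of 224 cassette exons. For the 53 exons listed from both sides, the inclusion in control cells implied from the 2 events correlated across exons (Pearson r = 0.936, Spearman coefficient 0.940, permutation p = 1e-05 for each, the smallest possible; r = 0.920 without the 2 exons farthest from the median). Exons are not independent replicates, and both values share the skipping junction.

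The gene lists were fixed before the data were examined: neurite outgrowth, axon guidance and adhesion; synapse; cytoskeleton and motors; splicing factors and RNA-binding proteins; chromatin and transcription; ion channels and transporters; DNA repair; cell cycle and mitosis; vesicle trafficking; neuron-enriched microexon genes; intellectual disability and microcephaly genes; and markers of astrocytes, the oligodendrocyte lineage, microglia and endothelium, neural progenitors and neurons. Members were matched by the table's symbol or the GENCODE symbol at the same splice sites. Direction in a list was compared with all other events by Fisher's exact test. Enrichment of a list could not be tested because the table holds no tested event above the threshold. Also fixed in advance was the rule for named genes: Pqbp1 and Ncam1; for each event type with at least 10 events the 4 largest changes in each direction; up to 4 members of each list with the largest absolute change; and genes with 3 or more events. The rule names 89 genes, and the text describes part of them. Genes named outside it are marked as chosen after their values were seen.

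The typing, applied to 4000 events simulated on simple gene models made to follow its rules, gave the right type in 100% of them. This checks the code alone. It does not measure how often real genes, with more transcripts and unannotated sites, are typed correctly. With cassette exons simulated as 65% lower at the real numbers, the test within types called them in 99.2% of 500 simulations and the test across types in 53.6%. With all types even, 2.2% of simulations had any call. Directions were drawn independently for each event, whereas 53 cassette exons were listed from both sides, always in the same direction. These rates therefore need not hold for the events as listed. A shift of the median by 0.5 standard deviations was called in 91 of 100 simulations with groups of 100 and 170 exons, and no shift in 7 of 100.

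Alternatives fixed in advance were the 25% of events with the smallest p, 1 event per gene and type, merging of overlapping events, and direction by gene for the lists. Added after seeing the data were each cassette exon counted once, cassette pairs from larger events, annotated junctions alone, a minimum change of 1 on the log2 scale, leaving out exons of 27 nt or shorter, and the lists on cassette exons alone. Of the explanations weighed for the patterns, double counting of exons is covered by the alternative with each exon once, and another difference between the libraries could not be tested; their separate tests were dropped. Flanking intron sequence and splice site features were not computed because no genome sequence was used here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.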

Results

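The data describe splicing in mouse cortical neurons after the messenger RNA of PQBP1, a nuclear protein that binds components of the spliceosome, was targeted with a short hairpin RNA. Mutations in the human gene cause X-linked intellectual disability. Neurons from the cortices of C57BL/6 mouse embryos received lentivirus and were collected on day 5 in vitro. PolyA RNA was sequenced from 2 samples with the PQBP1-targeting hairpin (knockdown) and 3 samples with a non-targeting hairpin (mock knockdown). The deposited table holds the authors' comparison of the groups: a p-value and a log2 fold, knockdown over control, for each of 1402 splice junctions in 585 alternative splicing events of 457 genes. It holds no value for any single sample and no read counts, so the depth behind each event and the spread between replicates are unknown. For that reason no standard deviation or n accompanies the folds below, and tests across events describe the listed events and not the samples.

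Each event is a set of junctions that share one splice site and differ at the other. Of the 585 events, 408 had 2 junctions and 177 had 3 or more. For a cassette exon with 2 junctions, the change in inclusion is given here as the ratio of the inclusion to the skipping junction in the knockdown, relative to the same ratio in the mock knockdown. For other event types the ratio is that of the nearer to the farther junction. Where either junction is rare, a large change of this ratio can be a small change in the share of inclusion. Coordinates are 1-based positions in mm10. Events were typed on gene models of the same assembly.

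Cassette exons made up most of the 2-junction events, and skipping was the more frequent direction. Inclusion was lower after knockdown in 173 cassette exon events and higher in 104, so 62.5% went towards skipping (95% Wilson interval 56.6% to 68.0%). The typing tries a cassette exon before mutually exclusive exons, so an exchange of exons can count here as skipping or inclusion. In Actn1, described below, the same exon is listed under both types. How many cassette exon events are exchanges was not examined. Neuronal genes moved both ways. An exon of Robo2, the axon guidance receptor for Slit proteins, had an inclusion ratio 0.305 times that of the mock knockdown. Exons of Ncam1, the neural cell adhesion molecule, and Agrn, the organizer of the neuromuscular synapse, were included more, at 2.25 and 4.33 times the mock ratio. The split departed from an equal one (exact two-sided binomial test, Benjamini-Hochberg adjusted p = 0.000323 over 8 event types). These events count 53 exons from both sides, and with each exon once 59.8% of 224 were lower (exact binomial test, adjusted p = 0.0317). Among the 73 cassette events that belong to the 147 events with the smallest p, 40 were lower and the split was not distinguishable from an equal one (exact binomial test, adjusted p = 0.483). With annotated junctions alone it was 58.8% lower (exact binomial test, adjusted p = 0.0518), and over all alternatives the adjusted p ran from 3.81e-05 to 0.483.

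**Figure D1:**
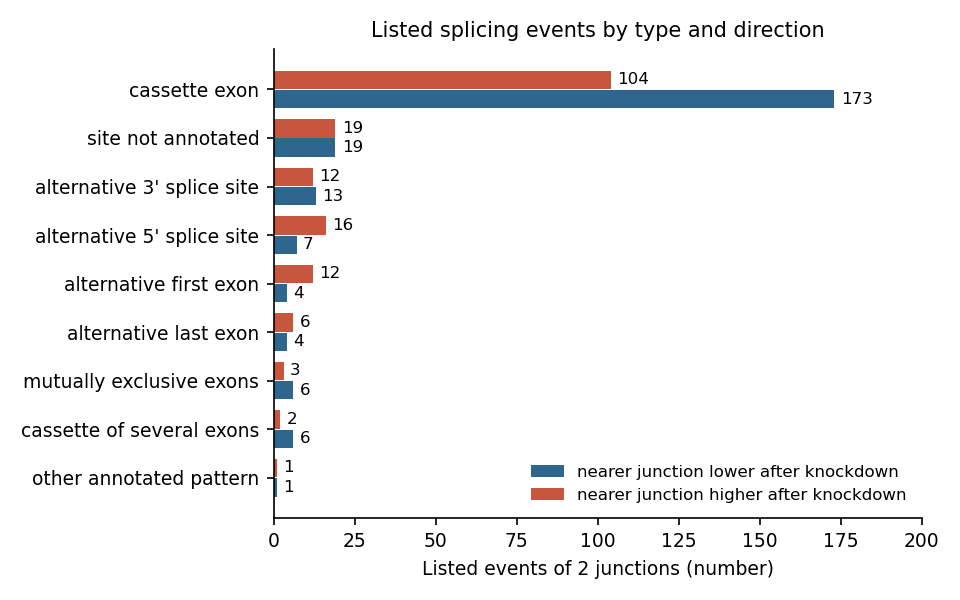
Number of listed 2-junction events (horizontal axis) of each event type, split by whether the nearer of the 2 junctions was lower (blue) or higher (red) after PQBP1 knockdown. For a cassette exon the nearer junction is the inclusion junction. Cassette exons show 173 events with lower and 104 with higher inclusion.

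The targeted gene, Pqbp1, has no event in the authors' deposited table. That table gives relative junction use and no gene levels, so the level of Pqbp1 after knockdown could not be checked here. Ncam1, which the study is known for and which was chosen on these samples, has 2 listed events. The first is a coding cassette exon of 30 nt on chromosome 9, positions 49550540 to 49550569. In the authors' deposited table its inclusion junction had a log2 fold of 0.99 and its skipping junction one of -0.18 (p = 0.00134). The second Ncam1 event is the choice of an alternative last exon at 49517278 to 49517582. The junction to this nearer last exon had a log2 fold of -1.16 and the farther one 0.09 (p = 0.0146) in the authors' deposited table. The ratio of the nearer to the farther last exon was therefore 0.420 times that of the mock knockdown.

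By this ratio, the largest shifts towards inclusion among cassette exons were in Palm, D7Ertd715e, 2610101N10Rik and Pdxdc1. The exon of Palm, which encodes the membrane-associated protein paralemmin, is a coding exon of 132 nt on chromosome 10 at 79816792 to 79816923, and its inclusion ratio was 6.97 times the mock ratio. The others stood at 5.50, 4.91 and 4.79 times. In 2610101N10Rik the log2 folds were 0.13 for inclusion and -2.17 for skipping in the authors' deposited table. Most of its ratio change thus lay in the rarer skipping junction. D7Ertd715e is the non-coding host transcript Snhg14 in the gene models used. By the same ratio, the largest shifts towards skipping were in Actn1, Acad8, Rps6kb2 and Col4a1. Actn1 encodes the actin crosslinker alpha-actinin. Its coding exon of 81 nt on chromosome 12 at 80170686 to 80170766 had an inclusion ratio 0.167 times that of the mock knockdown. The falling junction is not annotated and joins this exon to one of 66 nt, so it also makes up the second Actn1 cassette event (0.264 times) and shows less joint use of the 2 exons. In the third event, where the 2 exons are mutually exclusive, the ratio of the 81 nt to the 66 nt exon was 0.390 times. The exons of Acad8, Rps6kb2 and Col4a1 were at 0.167, 0.174 and 0.189 times. The median size of the change over the 277 cassette exon events was 1.35 on the log2 scale (interquartile range 1.0 to 1.71), against 1.42 in the other event types (permutation test, adjusted p = 0.460). Because the events were selected by p, these sizes describe the list and can overstate what an unselected event would show.

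**Figure D2:**
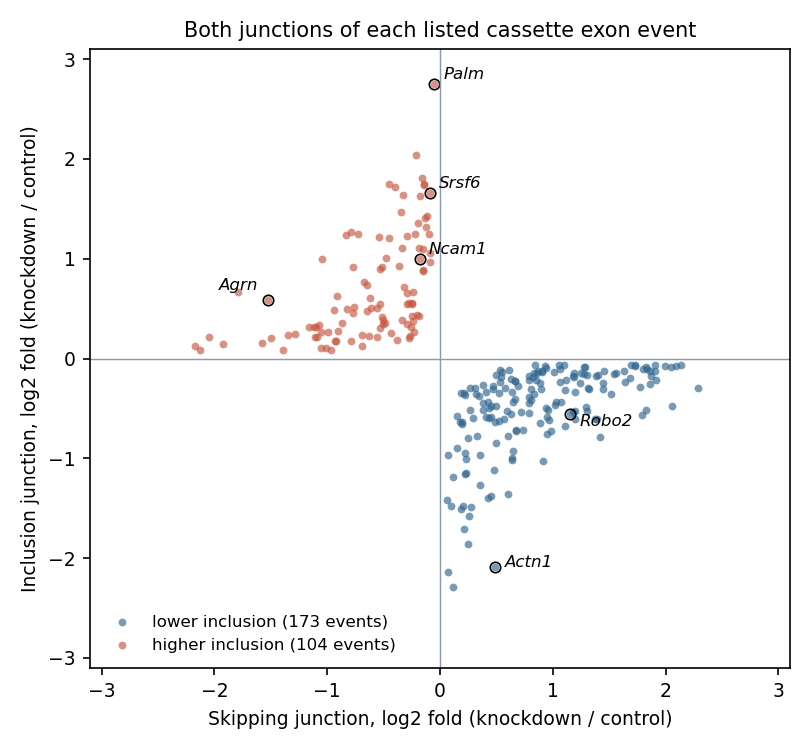
Log2 fold (knockdown over control, authors' values) of the skipping junction (horizontal axis) and of the inclusion junction (vertical axis) for each of the 277 listed cassette exon events, 173 with lower inclusion in blue and 104 with higher inclusion in red. The 2 junctions of an event moved in opposite directions throughout, and the circled points name genes described in the text.

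Cassette exons that were skipped more after knockdown were richer in G and C. The median GC content was 53.6% for exons with lower inclusion (interquartile range 47.4% to 58.3%) and 49.0% for exons with higher inclusion (45.3% to 53.6%). The difference, -4.62 percentage points for higher minus lower inclusion, passed the permutation test (adjusted p = 0.00188 over 4 exon features). With each exon counted once it was -4.51 points (permutation test, adjusted p = 0.00312). Exons of 27 nt or shorter, a class that includes neuronal microexons, made up 14.4% of events with higher inclusion (95% Wilson interval 8.94% to 22.4%) and 6.36% of those with lower inclusion (3.59% to 11.0%). That difference did not pass after adjustment (Fisher's exact test, adjusted p = 0.0661). These events count some exons from both sides. With each exon counted once the adjusted p of Fisher's exact test was 0.312, and with 1 event per gene and type it was 0.199. Macf1, the microtubule-actin crosslinker, and Cadps, a regulator of dense-core vesicle release, have such exons with higher inclusion (18 and 21 nt, 3.27 and 3.72 times the mock ratio). In Dync1i2, a dynein intermediate chain, an exon of 18 nt was at 0.216 times. The length was a multiple of 3 in 67.3% of the higher and 67.6% of the lower events (Fisher's exact test, adjusted p = 1). Median lengths were 91.5 and 90 nt (permutation test, adjusted p = 0.939).

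**Figure D3:**
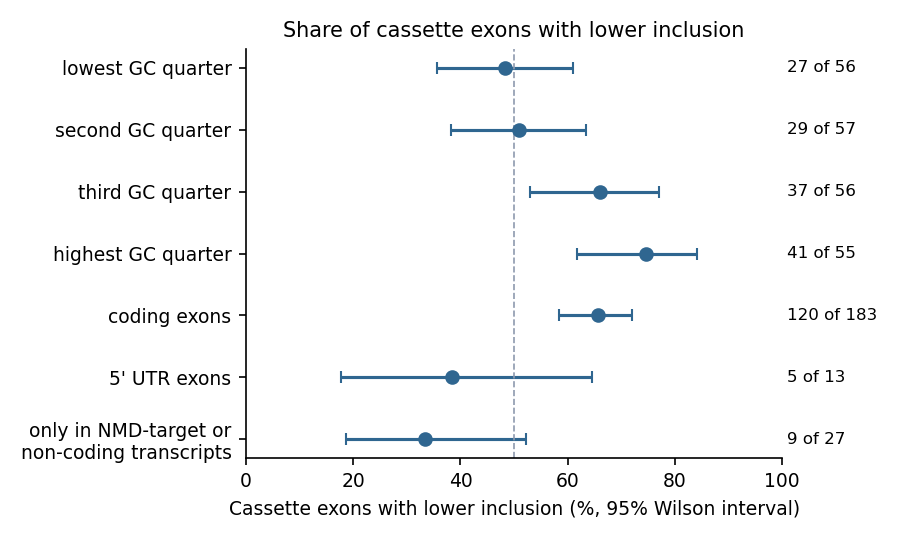
Percent of cassette exons with lower inclusion after PQBP1 knockdown (points, with 95% Wilson intervals), each exon counted once, in 4 classes of exon GC content and by annotation of the exon, both chosen after the data were seen. The share was 48.2% in the class of lowest and 74.5% in that of highest GC content, and the dashed line marks an equal split.

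Alternative 5' splice sites and first exons had the opposite balance from the rest of the list. In 16 of 23 alternative 5' splice site events the nearer site, which gives the longer exon, was used more after knockdown. Examples are Rnf32 at 6.71 times the mock ratio, Hspd1, the mitochondrial chaperone HSP60, at 4.63 times, and Dcaf5 at 4.53 times. S100pbp and Nfib, a transcription factor of neural development, went the other way, at 0.216 and 0.273 times. Of 16 alternative first exon events, 12 moved towards the first exon nearer to the shared acceptor. These include Camk2b, a kinase of synaptic plasticity (3.91 times), Nedd4l, a ubiquitin ligase (3.37 times), and Slc2a3, a neuronal glucose transporter (2.72 times). Npcd, at 0.355 times, moved away from it. Compared with all other event types, the share with the nearer junction lower was 30.4% against 58.7% for 5' splice sites and 25% against 58.4% for first exons (Fisher's exact test, adjusted p = 0.0262 for each). Most of those other events are cassette exon events, which lean lower and count some exons from both sides. Contrasts of these classes with the non-cassette types alone, or with each cassette exon counted once, were not run. Cassette exons, at 62.5% against 45.8%, differed from the other types too (odds ratio 1.97, Fisher's exact test, adjusted p = 0.0149). Within the 5' splice site and first exon classes alone the split was not distinguishable from an equal one (exact binomial test, adjusted p = 0.248 for each). The contrasts of these classes with other types were lost with annotated junctions alone (Fisher's exact test, adjusted p = 0.0557 for each), and the 5' splice site contrast also among changes of at least 1 on the log2 scale (adjusted p = 0.0574). With each cassette exon counted once the cassette contrast had an adjusted p of 0.0518.

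The remaining classes were close to balanced or too small to test with any precision. Alternative 3' splice sites split 12 higher to 13 lower, with Metap2 (5.26 times) and Alkbh1 (5.12 times) the largest shifts to the nearer site and Crem, a cyclic AMP responsive factor, at 0.273 times. Of 10 alternative last exon events, 6 moved to the nearer exon. Tmod3, which caps actin filaments, was among them at 2.73 times, and Arpp21 at 3.82 times, whereas Opn3 was at 0.206 times. Mutually exclusive exons included Snap25, a SNARE protein of synaptic vesicle fusion that uses either of 2 exons of 118 nt on chromosome 2. The ratio of the exon at 136769743 to 136769860 to its alternative was 1.79 times that of the mock knockdown when read from the upstream donor. Read from the downstream acceptor, where the nearer junction belongs to the exon at 136770057 to 136770174, the ratio was 0.603 times, the same direction of exchange. In 38 events a splice site was not annotated, and these had larger changes of the ratio than the rest (median 1.65 against 1.34 on the log2 scale, permutation test, adjusted p = 0.0430). Whether their junctions were rarer than those of other events was not examined. Ptpru, a receptor phosphatase, at 6.74 times and Lrrc8a, a volume-regulated channel subunit, at 0.141 times were the extremes.

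Of the 12 gene lists with a 2-junction event, splicing factors and RNA-binding proteins were the only one that passed the test of direction. Of the 159 listed symbols, 25 had an event, and 18 of their 23 two-junction events moved towards the nearer junction (78.3%, against 40.8% of all other events). An exon of Prpf4b, a kinase of the spliceosome, lies on chromosome 13 at 34893317 to 34893422 in transcripts annotated as targets of nonsense-mediated decay or non-coding, and was included at 3.67 times the mock ratio. A cassette exon of 165 nt in Srsf6, a serine/arginine-rich splicing regulator, on chromosome 2 at 162932815 to 162932979 stood at 3.36 times. Rbm25 and Hnrnpa2b1 events with unannotated sites were at 4.08 and 4.12 times, while a second Hnrnpa2b1 event went the other way (0.527 times). The list passed Fisher's exact test (adjusted p = 0.00879 over 12 lists). Counting genes instead of events, with mixed genes left out, 14 of 18 moved that way and Fisher's exact test was not passed (adjusted p = 0.0707). With cassette exons alone, each counted once, it was 10 of 13 (Fisher's exact test, adjusted p = 0.0757), and over the 4 alternatives the adjusted p ran from 0.0281 to 0.0757.

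The 12 neurite outgrowth, axon guidance and adhesion genes with an event split evenly, 8 events higher and 8 lower (Fisher's exact test, adjusted p = 0.918). Besides Ncam1, Robo2 and Agrn, Nrcam, an axonal adhesion molecule of the L1 family, took up a cassette of several exons at 4.52 times the mock ratio. Sema4d, a semaphorin, included an exon of its 5' UTR at 3.90 times. The Agrn exon of 24 nt lies on chromosome 4 at 156168546 to 156168569. In the authors' deposited table its inclusion junction had a log2 fold of 0.58 and its skipping junction one of -1.53 (p = 0.000116). Robo2 included less of its coding exon of 126 nt on chromosome 16 at 73933046 to 73933171, with log2 folds of -0.56 for inclusion and 1.16 for skipping (p = 1.79e-05) in the authors' deposited table.

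Among 16 synaptic genes with an event, 9 two-junction events were higher and 17 lower (Fisher's exact test against all other events, adjusted p = 0.918). Snap25, whose exchange was listed from both sides, enters this tally in both directions. Gria2, a subunit of AMPA-type glutamate receptors, had a coding exon of 115 nt on chromosome 3 at 80690404 to 80690518 included less. Its ratio was 0.433 times the mock ratio from the downstream side and 0.384 times from the upstream side. The typing looks for a cassette exon before mutually exclusive exons, so whether this exon was exchanged for another was not examined. Camk2b and Nrxn2, a neurexin, each had 5 listed events, the most of any gene. In Nrxn2 an exon of 90 nt rose to 1.40 and 1.41 times from its 2 sides, and exons of 24 and 27 nt were at 0.679 and 0.498 times. Kif1a, a kinesin of synaptic vesicle transport, had an event with an unannotated site at 0.278 times. Cask, a scaffold linked to intellectual disability, took up an exon of 36 nt at 2.28 times.

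The cytoskeleton and motor list had 10 events higher and 12 lower in 19 genes, chromatin and transcription 4 and 12 in 15 genes, and ion channels and transporters 2 and 6 in 9 genes. None of these passed (Fisher's exact test, adjusted p = 0.993, 0.918 and 0.918). Actn1, Dync1i2 and Macf1, described above, and Tln2, a talin (3.12 times), led the first. Atrx, a chromatin remodeller linked to intellectual disability (4.12 times), and Mll3, a histone methyltransferase (3.73 times), moved towards the nearer junction, against the direction of most events of this list, such as those of Nfib and Crem, described above. Among channels and transporters, Atp2b1, a calcium pump (0.287 times), and Slc12a2, a chloride cotransporter (0.289 times), went towards skipping. Cacna1b, a presynaptic calcium channel, was at 0.346 times, and Kcnd3, a potassium channel, at 2.50 times. The neuron-enriched microexon genes had 5 events higher and 7 lower (Fisher's exact test, adjusted p = 1), among them Zfp207 at 0.227 times, Agrn, and Ppfibp1 at 0.254 times. Genes of intellectual disability and microcephaly split 4 and 4 (Fisher's exact test, adjusted p = 0.972), with Huwe1, a ubiquitin ligase, at 0.281 times. DNA repair had 1 higher, Xpa at 2.94 times, and 1 lower, Fance at 0.401 times (Fisher's exact test, adjusted p = 1). Both cell cycle events were the 2 sides of 1 exon of Cdk4, which was lower, at 0.624 and 0.637 times. Both 2-junction events of vesicle trafficking genes were lower, Agap3 at 0.427 and Rab6a at 0.586 times. The Rab6a event is of mutually exclusive exons, so its direction depends on the side from which it is read. Of the neuron markers, Rbfox3 (2.84 times) and Snap25 had events, Snap25 in both directions for the same exchange. The adjusted p of Fisher's exact test was 0.918 for cell cycle, vesicle trafficking and neuron markers alike. No astrocyte, oligodendrocyte, microglia, endothelial or neural progenitor marker did, which the table cannot set against their levels.

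Several genes had more than one listed event, which for many are the 2 sides of one exon. Of the 457 genes, 102 had 2 or more listed events and 20 had 3 or more. Nnat, which encodes the small membrane proteolipid neuronatin, had the smallest p in the authors' deposited table (4.45e-09), for an event with 5 junctions on chromosome 2. There the junction spanning 157561294 to 157561541 had a log2 fold of -0.50, and the junction spanning 157560261 to 157561541, which skips the exon before it, one of 0.40, in the authors' deposited table. Cadm1, a synaptic adhesion molecule, had a coding exon of 33 nt at 0.272 times the mock ratio. The junction spanning 47829410 to 47848166, which leaves this exon, rose in both larger Cadm1 events (log2 folds of 0.35 and 0.33 in the authors' deposited table). In the first of them the junction spanning 47836771 to 47848166, from another exon, fell (-0.61). The skipping junction passes over both exons, so the ratio is not a measure of the 33 nt exon alone. Mtap4, a microtubule-associated protein, lost a coding exon of 222 nt on chromosome 9 (0.509 and 0.525 times from its 2 sides), and Kdm1a, a histone demethylase, an exon of 147 nt (0.540 and 0.560 times). Pam, an enzyme of peptide amidation, gained one of 318 nt (2.68 and 2.34 times). Altogether 53 cassette exons were listed from both sides, all 53 with the same direction from each, 39 of them lower. Both events of such an exon share the skipping junction, so they are not independent.

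All 585 events have a smallest junction p under 0.05 in the authors' deposited table, which names no adjustment for the number of events tested. The tests of their spread were chosen after the values were seen. For the 2-junction events, 213 had p under 0.025 and 195 had p of 0.025 or more, a split not distinguishable from even (exact two-sided binomial test, p = 0.400). In the lowest part of the range, p under 0.005, there were 55 events, 13.5% against 10% for an even spread (exact binomial test, p = 0.0254).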

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

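The alternatives that counted each cassette exon once, used annotated junctions or cassette exons alone, required a minimum change, left out short exons or added pairs from larger events were chosen after seeing the data. Of 143 values under an alternative, 122 were not reversed and kept their side of the threshold, or for counts stayed within 1.5 times. An even split was taken to have no direction to reverse. Many of the 122 are counts or differences that no setting called, so they say little about the results that passed. The others were 4 counts that moved, 9 reversed values, and 8 values that missed the threshold although the main result passed. Among the 25% of events with the smallest p, 147 in number, were 40 cassette events with lower and 33 with higher inclusion. The share lower was then 54.8% (exact binomial test, adjusted p = 0.483) with fewer events tested. Between cassette events with p under 0.01 (56.0% lower) and the rest (64.9%) no difference was detected (Fisher's exact test, p = 0.209). A change of at least 1 on the log2 scale left 312 events, and the 5' splice site odds ratio of 0.302 then missed the threshold. Annotated junctions alone gave 58.8% lower cassette events and odds ratios of 0.343 for 5' splice sites and 0.264 for first exons, and none of these 3 then passed. Each cassette exon counted once gave a cassette odds ratio of 1.76, which also missed it. The splicing-factor list missed it by gene (77.8%) and with cassette exons counted once (76.9%). The cause of these losses was not tested.

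Changes of direction occurred only in differences that no setting called. The share of lengths that are a multiple of 3 differed between directions by 0.861 points with 1 event per gene, 0.995 with each exon once and 1.18 with annotated junctions. Alternative 3' splice sites were 44.4% lower at a change of at least 1. For the lists, a change of direction means that the share higher moved to the other side of that in all other events. The cytoskeleton list was 45.5% higher in the main analysis, 41.2% with each exon once and 38.5% with cassette exons once. The microexon list was 41.7% both in the main analysis and with cassette events alone, so there only the share in other events moved. By gene, the neurite list was 44.4% and the intellectual disability list 40.0% higher. No paired analysis was possible because the table has no values per sample. For the same reason leaving out replicates, other tests and filters on low values were not run. Minimum changes in inclusion of 0.1 and 0.2, a minimum of 20 reads and intron windows of 100 or 200 nt were not run, as inclusion levels, reads and a genome sequence were not used here. Depth is unknown, so which events rest on few reads cannot be said.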

Other observations

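Apart from the 2 tests that compare GC content at the exon ends, the tests in this part were chosen after the results they bear on had been seen, as were the genes named here outside the fixed rule. Of the 7 cassette exons of the splicing-factor list found only in decay-target or non-coding transcripts 6 gained inclusion, as did 3 of its 5 coding ones, in Ewsr1, Elavl2 and Srsf6 (Fisher's exact test, p = 0.523). Snrnp70 and Snrpb, which encode proteins of the spliceosomal snRNPs, Srsf11, a serine/arginine-rich protein, and Bclaf1 each took up an exon annotated only in targets of nonsense-mediated decay or non-coding transcripts. Inclusion ratios were 2.92, 2.37, 1.88 and 2.54 times those of the mock knockdown, beside Prpf4b at 3.67 times. A second exon of Snrnp70 in this class, at 1.54 times, overlaps the first and shares its skipping junction, so the 6 are not all independent. Srsf2, another serine/arginine-rich factor, took up an exon of 104 nt in its 3' UTR at 2.21 times. The 5 events of the list that went the other way were of Cirbp, Celf4, Hnrnph3, Hnrnpa2b1 and Rbm4, at 0.386, 0.482, 0.499, 0.527 and 0.537 times. Of these, the cassette exon of Celf4 is of the same annotated class, and those of Hnrnph3 and Rbm4 are coding.

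Over all genes, 18 of 27 cassette exons found only in decay-target or non-coding transcripts gained inclusion, against 63 of 183 coding exons (Fisher's exact test, p = 0.00245). Where any fitting annotated exon being coding counts as coding, it was 16 of 25 against 65 of 185 (Fisher's exact test, p = 0.00791). The classes depend on how exons were reconstructed. An Arhgap21 exon of the first class, at 20853958 to 20853978, shares its start and skipping junction with a coding one at 20853958 to 20854232. They may be the sides of the same exon, which is then counted in both classes. An Agrn exon of the first class, at 156167777 to 156168569, spans the listed intron 156167810 to 156168545. Its inclusion junction may therefore belong to a shorter exon. Without splicing-factor genes the classes still differed (Fisher's exact test, p = 0.0271). That test used the first assignment of classes and was not repeated under the stricter one or without the Arhgap21 and Agrn exons. Splicing-factor genes as the whole cause therefore stay open. The inclusion junction being the rarer one stays open: among such exons Fisher's exact p was 0.0419 with the rarer taken by average use, 0.0642 by use in both groups, 0.311 by mock alone and 0.00161 by knockdown alone. So does lower GC content: at or below the median GC content the difference was 12 of 17 against 38 of 85 (Fisher's exact test, p = 0.0649), and a difference between the libraries other than PQBP1 was not testable.

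For the excess of cassette exons with lower inclusion, rare junctions being called upwards more easily with 2 knockdown and 3 mock libraries is argued against as the whole cause, by tests and ways of taking the rarer junction that were set after values had been seen. The rarer by use averaged over the groups rose in 51.0% of exons where it was the inclusion junction and in 68.3% where it was the skipping junction (Fisher's exact test, p = 0.0128; by mock alone 63.4% and 76.3%, p = 0.0516; by knockdown alone 41.2% and 60.6%, p = 0.00464; by both groups 54.1% and 71.3%, p = 0.0190), at a similar median use of 24.4% and 22.1%. In other event types it rose in 48.9% (95% Wilson interval 40.5% to 57.3%) by the average and 50.4% (41.4% to 59.4%) by both groups. The shares were 56.5% by mock (47.9% to 64.7%) and 44.3% by knockdown (36.1% to 52.8%), which each lean 1 way because they pick on 1 side of the change. By mock the contrast between inclusion and skipping junctions missed the threshold. The argument therefore rests on taking the rarer by the average or by both groups. GC content stays open: the share lower was 49.6% at or below the median exon GC content and 70.3% above it (Fisher's exact test between the groups, p = 0.00176), as a loss of GC-rich fragments from the knockdown libraries could give, and as exons of a GC-rich class depending on PQBP1 could give. A loss that acts at the junction is argued against by cassette exons whose end is GC-poorer than the exon joined on skipping, of which 62.7% were still lower (53.4% to 71.2%), while in other event types the junction with the GC-richer end fell in 55.4% (44.7% to 65.6%), which does not decide.

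The near-even spread of p up to 0.05 is what a list with many chance calls at an unadjusted p would have. The excess of 2-junction events below 0.025 over those above it was 4.41% of all such events, but that spread is what raised the explanation and so does not support it. The number of events tested is not known, so the share of chance calls cannot be given, and a test that is conservative at small p could give the same spread.

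Cassette exons with a skipping junction that is not annotated went towards skipping in 23 of 29 cases (79.3%, 95% Wilson interval 61.6% to 90.2%), against 109 of 192 exons with both junctions annotated (56.8%, 49.7% to 63.6%; Fisher's exact test between the groups, p = 0.02496). The exons with both junctions annotated were not distinguishable from an equal split (exact binomial test, p = 0.0709). How rare the unannotated skipping junctions were was not examined.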
